A study of Homo sapiens with 10 samples.

How the data were processed

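Polyadenylated RNA of 786-O cells, a human clear cell renal carcinoma line, was sequenced in 10 libraries, 2 per group. The groups were DMSO for 12 h and PT2399, an inhibitor of the transcription factor HIF-2α, at 2 µM for 3, 6, 9 or 12 h. Libraries came from a strand-specific kit and were sequenced as read pairs of 42 bases per read, per the labels' protocols. Each library's group and replicate number were taken from its title. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. DMSO was collected at 12 h only, so the 3, 6 and 9 h libraries had no control of their own time.

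The tools named are STAR, Picard, HTSeq and DESeq2, with genome build hg19, per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap, antisense genes and near-identical paralogs such as the metallothioneins are therefore uncertain where reads could be split between them. The reference used here had another build than hg19, so no coordinates are given, and it served for older gene symbols, transcript lengths and 3' untranslated regions.

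The deposited signal values are normalized gene counts, each library's reads divided by 1 size factor by the authors. The values of each library were whole multiples of the value of 1 read, and 100% of them came out whole within 0.01 of a read, so read counts were recovered. Reads in genes ranged from 8073303 to 13560867 per library, with a median of 11116400. The 2 deposited entries that name no gene, reads outside genes (6.18% to 6.80% of a library) and reads ambiguous between genes (2.87% to 2.92%), were left out of library sizes and tests. The table held 11912 genes, the lowest with a mean value of 9.60. Genes with lower values were not analysed here, and 15 genes under a mean of 10 were not tested.

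The authors also deposited 4 comparison tables from DESeq2, 1 per PT2399 time, per the file headers. Their deposited log2 fold changes are positive where DMSO was higher, as a comparison with the deposited normalized counts showed, and signs were turned here to give PT2399 over DMSO. The tables also hold deposited score columns, the standard error and the Wald statistic, and deposited p-value columns, unadjusted and adjusted. A DESeq2 fit over all 10 libraries gave the deposited log2 fold changes to within 4.8e-05.

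The main test was limma 3.58.1 in R 4.3.3 (moderated, two-sided, with a trend on the mean) on log2(normalized count + 1). It used 11897 genes and 1 linear model with a mean per group over all 10 libraries, which left 5 residual degrees of freedom beside 59.4 prior ones. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes at an adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Contrasts were each PT2399 time against DMSO, 12 h against 3 h, and the least-squares slope per hour over the 4 PT2399 times. With 2 libraries against 2, an exact permutation test cannot go below a p of 0.333, so single values rest on the model.

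Of 24 gene lists written from general knowledge, 22 had at least 5 measured genes and were tested. The 13 genes of the mitochondrial genome had 0 measured, and the 16 replication-dependent histone genes had 2. Each list was tested with limma's camera (two-sided, correlation preset at 0.01, Benjamini-Hochberg over lists within a contrast), again with an estimated correlation per list, and with fry. Another 3 lists (metallothioneins with the zinc exporter SLC30A1, NRF2 targets and fatty acid oxidation) were written after the data were seen and were adjusted apart. Named genes followed a rule: the 10 largest increases and decreases at 12 h, and the 3 largest at the other contrasts, among called genes with a mean of at least 50 whose treated libraries both lay on one side of both DMSO libraries; 18 fixed genes; and up to 4 members of each list with the smallest adjusted p at 12 h, of which mainly those that were called are named. Other genes named were chosen after their values were seen, and these are marked. The contrasts above, tests, lists (apart from the 3 added), naming rule and alternatives were fixed before the data were examined. The contrasts between successive PT2399 times, with their alternatives, and the alternatives for the genes that moved back by 12 h were added after the data were seen.

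On simulated data for the 12 h contrast (5 simulations over a mean of 11855.4 genes, 200 of them changed), limma's calls were 4.97% false. It recovered 80.8% of genes changed by 0.5 on the log2 scale, 91.5% at 1 and 99.7% at 2. DESeq2 1.42.0 recovered 62.9%, 82.7% and 97.4%, with 0.373% of its calls false, and edgeR 4.0.16 recovered 81.4%, 92.1% and 99.7%, with 5.45% false. Camera called 0 of 100 lists without a change. The simulated genes varied independently, so this does not check camera for lists whose genes vary together. Each simulated gene had the same dispersion in all groups, and changes were at least 0.5. The simulation therefore checks neither a larger spread between the 12 h libraries nor changes as small as many of those called. The false share among the real calls at 12 h may differ. The alternatives were pseudocounts of 0.25 and 5, no filter and a minimum mean of 50, rescaling by TMM factors, quantile normalization, the replicate number as a block, a fit on the libraries of the contrast only, edgeR's quasi-likelihood test and DESeq2 on recovered reads, and leaving out each library in turn.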

Results

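The data are gene expression profiles of 786-O cells, a clear cell renal carcinoma line that lacks functional VHL, the protein that marks HIF-2α for degradation. Cells were grown in serum at atmospheric oxygen and received DMSO for 12 h or 2 µM PT2399, which blocks the pairing of HIF-2α with its partner ARNT, for 3, 6, 9 or 12 h. There were 2 libraries per group, and all values below are normalized counts as mean ± SD with n = 2. Reads in genes ranged from 8073303 (3 h, replicate 1) to 13560867 (9 h, replicate 2), and counting noise was therefore higher in the 3 h libraries. The 10 most abundant genes held 4.52% to 5.19% of the reads of a library. Counts of the 2 libraries of each group differed by more than sampling noise, so no library was counted as a copy of another. The chi-square per degree of freedom was 1.26 for DMSO, 3 h and 6 h, 1.43 for 9 h and 1.99 for 12 h. The main model shares its spread over all groups, so it may understate the spread at 12 h. The series asks how the transcriptome of these cells responds over hours to loss of HIF-2 activity, and its title places the work among studies of nuclear speckles.

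After 12 h of PT2399, genes of the hypoxia response were among the most strongly lowered transcripts. DDIT4, an inhibitor of mTORC1 signaling, went from 2223 ± 39.6 in DMSO to 345.8 ± 13.0, 6.42 times lower (log2 fold change -2.68, SE 0.0679, limma with Benjamini-Hochberg adjustment, adjusted p = 3.11e-43). SLC2A1, the glucose transporter GLUT1, went from 11072 ± 174 to 3011 ± 81.3, 3.68 times lower (log2 fold change -1.88, SE 0.0338, limma adjusted p = 4.83e-52). Other large decreases among genes with a mean of at least 50 were those of F3, the clotting initiator tissue factor (2135 ± 74.6 to 478.9 ± 20.4, 4.45 times lower), ADM, the vasodilator peptide adrenomedullin (4.08 times), and NDRG1, a hypoxia-induced stress gene (2351 ± 31.4 to 632.1 ± 60.8, 3.72 times). C10orf10 was 3.63 times lower, the semaphorin SEMA4B 3.19 times, the prolyl hydroxylase EGLN3 3.16 times, the EGF receptor inhibitor ERRFI1 2.93 times and MYEOV 2.91 times. CCND1, which encodes cyclin D1 and is a HIF-2 target in these cells, fell from 6526 ± 8.39 to 2362 ± 39.3, 2.76 times lower, and VEGFA, the angiogenic growth factor, from 2159 ± 65.5 to 803.0 ± 77.1, 2.69 times lower. Smaller decreases passed the test for TGFA (1.62 times), the lipid droplet protein PLIN2 (1.48 times) and IGFBP3 (1.28 times).

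**Figure D1:**
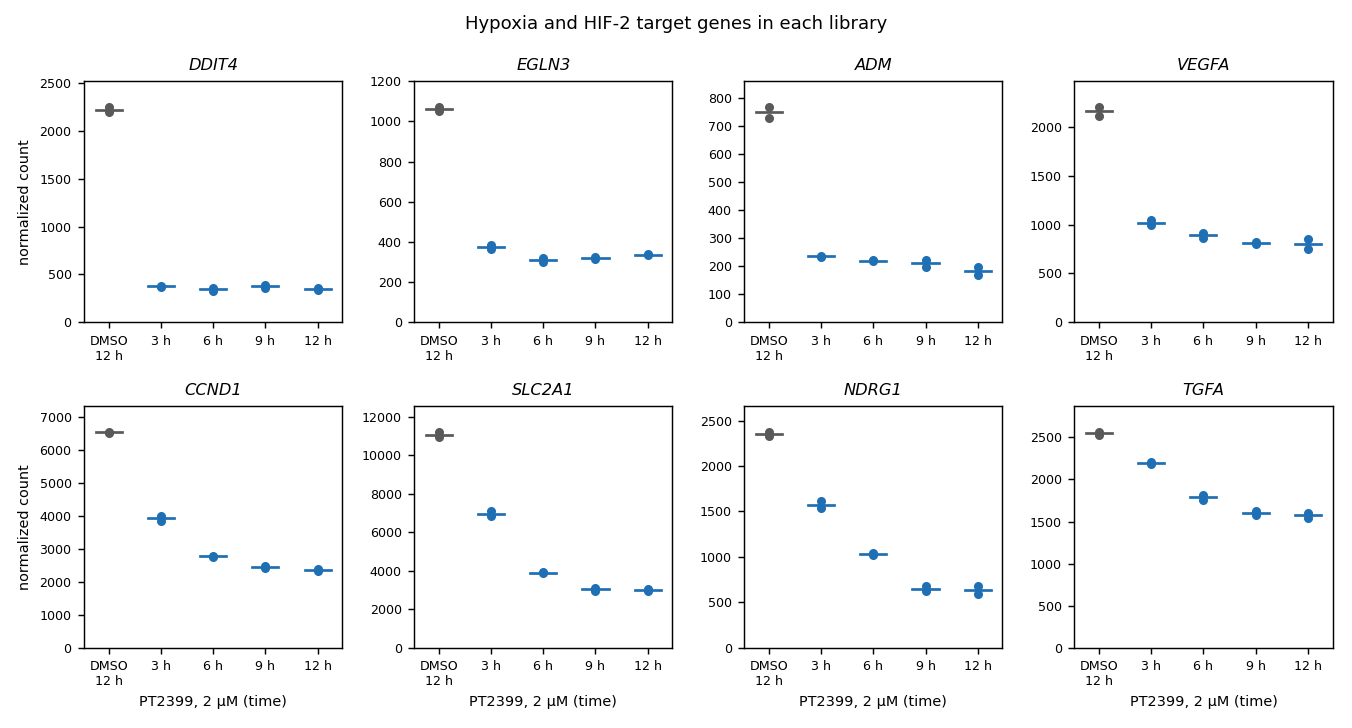
Normalized count (vertical axis, from 0) of 8 hypoxia and HIF-2 target genes in DMSO at 12 h (grey) and after 3, 6, 9 and 12 h of 2 µM PT2399 (blue); points are libraries and bars are means of 2. DDIT4 and EGLN3 stood near their 12 h level at 3 h, whereas SLC2A1, NDRG1 and TGFA were at 6966, 1573 and 2194 at 3 h and at 3011, 632.1 and 1575 at 12 h.

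Of the 40 measured genes in the list of HIF-2 and hypoxia targets, 28 fell, 1 rose and the rest did not pass the test (28 fell and 2 rose when adjusted over the list alone). The mean log2 change of the list was -0.60 (camera adjusted p = 7.41e-53, and 0.000231 with an estimated correlation). The single riser was VLDLR, the very low density lipoprotein receptor (0.29, named after its value was seen). Glycolysis genes fell together: 12 of 25 were lower and 0 higher (14 lower when adjusted over the list alone), with a mean of -0.21 (camera adjusted p = 6.96e-13, and 0.00362 with an estimated correlation). Besides SLC2A1 these included hexokinase 2 (HK2, 640.9 ± 1.48 to 419.9 ± 22.6), ENO2 (log2 fold change -0.46) and ALDOA (-0.27). In the NF-kB and inflammatory cytokine list, 15 of 19 genes fell and 0 rose (16 fell when adjusted over the list alone), with a mean of -0.60 (camera adjusted p = 1.55e-20, and 0.00362 with an estimated correlation). CXCL8, the neutrophil chemokine interleukin 8, went from 393.2 ± 0.279 to 140.7 ± 5.68, 2.78 times lower, and the log2 fold changes of the apoptosis inhibitor BIRC3, the adhesion receptor ICAM1 and the cytokine LIF were -0.72, -0.64 and -0.35.

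Among immediate early genes, 7 of 19 fell and 0 rose (8 and 1 when adjusted over the list alone), among them DUSP1 (-0.87), JUNB (-0.47), KLF6 (-0.37) and FOSL1 (-0.36). The list passed the preset test (camera adjusted p = 5.42e-05) but had an adjusted p = 0.121 with an estimated correlation. Proliferation genes moved by small amounts. Of the DNA replication list 7 of 43 fell (8 when adjusted over the list alone), led by MCM4 (-0.16), MCM7 (-0.14), POLE (-0.17) and RRM2 (-0.11), with camera adjusted p = 0.00178 and an adjusted p = 0.230 with an estimated correlation. Of the mitosis list 9 of 35 fell (10 when adjusted over the list alone), led by CDC20 (-0.17), FOXM1 (-0.19), TPX2 (-0.13) and UBE2C (-0.16), with camera adjusted p = 0.00464, an adjusted p = 0.121 with an estimated correlation and 0.461 after quantile normalization. Of the cytosolic ribosomal proteins 10 of 47 fell (12 when adjusted over the list alone), among them RPS24 (-0.13), RPLP0 (-0.11) and RPL3 (-0.11, but 0.014 after quantile normalization). Their camera adjusted p was 5.42e-05, and an adjusted p = 0.423 resulted with an estimated correlation and 0.828 after quantile normalization. Heat shock genes were the one fixed list with a higher mean that passed the preset test (camera adjusted p = 0.00610, adjusted p = 0.355 with an estimated correlation): 3 of 11 rose, over all genes and when adjusted over the list alone, namely HSPH1 (0.13), HSP90AA1 (0.10) and DNAJA1 (0.12).

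Genes of metal handling led the increases at 12 h among genes with a mean of at least 50. MT1F, a metallothionein that binds zinc and copper, went from 48.08 ± 8.44 to 213.3 ± 9.54, 4.40 times higher (log2 fold change 2.14, SE 0.133, limma with Benjamini-Hochberg adjustment, adjusted p = 1.76e-21). MT1X went from 267.3 ± 11.1 to 812.4 ± 3.44, 3.03 times higher, MT1E from 1673 ± 83.8 to 3009 ± 7.91, 1.80 times higher, and the zinc exporter gene SLC30A1 from 298.4 ± 30.6 to 547.9 ± 1.85, 1.84 times higher. Metallothionein genes are close paralogs, so reads of single members are uncertain. The other large increases were SMIM10 (2.05 times), the presynaptic scaffold gene PCLO (1.92 times), the growth factor receptor FGFR2 (294.9 ± 20.1 to 510.2 ± 28.2, 1.73 times), and the potassium channel KCNJ16 (56.76 ± 11.4 to 100.1 ± 29.3, 1.73 times). They were followed by the p53-induced oxidoreductase TP53I3 (1.72 times) and fibrillin 1 (FBN1, 1.69 times). The call for KCNJ16 was lost without DMSO replicate 2 (limma adjusted p = 0.0843) or without 12 h replicate 2 (0.168), and that for TP53I3 without DMSO replicate 1 (0.0533) or without 12 h replicate 2 (0.0553).

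Several lists did not pass camera at 12 h, most with genes in both directions. The integrated stress response list had 5 of 24 genes higher and 5 lower (the same numbers when adjusted over the list alone; camera adjusted p = 0.536): the pseudokinase TRIB3 was 1.99 times lower, the amino acid transporter genes SLC7A5 and SLC3A2 fell by 0.69 and 0.32 on the log2 scale, and the cystine transporter SLC7A11 rose by 0.44. Of the cholesterol synthesis genes 6 of 24 rose and 2 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.138), with FDFT1 (0.31), IDI1 (0.24) and HMGCS1 (0.16) higher and INSIG1 (-0.23) lower. Of the matrix list 4 of 26 rose and 8 fell (4 and 9 when adjusted over the list alone; camera adjusted p = 0.230), with thrombospondin 1 (THBS1, 0.35) higher and PLOD2 (-0.26), TGFB1 (-0.30) and MMP2 (-0.35) lower. Of the kidney epithelium genes 2 of 11 rose and 3 fell (the same numbers when adjusted over the list alone; camera adjusted p = 0.742), with cadherin 6 (CDH6) 1.41 times higher and KRT18 (-0.20), PAX8 (-0.20) and KRT19 (-0.19) lower. Ribosome biogenesis genes had 2 of 33 higher and 7 lower (2 and 10 when adjusted over the list alone; camera adjusted p = 0.0508), with UBTF (0.28) higher and LDHA (-0.22), DDX21 (-0.15) and PES1 (-0.16) lower. The p53 target list had 3 of 24 higher and 1 lower (the same numbers when adjusted over the list alone; camera adjusted p = 0.517), with GADD45A (0.24) and RRM2B (0.22) higher besides TP53I3 and the death receptor TNFRSF10B (-0.66) lower. ER chaperones had 2 of 20 higher, HSPA5 (0.15) and DNAJB9 (0.49), and HERPUD1 (-0.30) lower (3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.113). After quantile normalization the mean of that list went from 0.049 to 0.086 and the list passed (camera adjusted p = 0.000136), as it did at 3, 6 and 9 h (0.0499, 0.000567 and 9.43e-06). With an estimated correlation, without that normalization, it had an adjusted p = 0.355 at 12 h and 0.404, 0.513 and 0.295 at 3, 6 and 9 h. Of the 19 interferon genes 2 rose, among them IFIH1 (0.43), and 0 fell (2 also when adjusted over the list alone; camera adjusted p = 0.230). Of the oxidative phosphorylation genes SDHB (-0.16), COX7B (-0.19) and ATP5B (-0.092) fell and 0 of 35 rose (3 and 0 when adjusted over the list alone; camera adjusted p = 0.265). Of the circadian clock genes BHLHE40 (-0.52), NFIL3 (-0.28) and TEF (-0.38) fell and PER1 (0.44) rose of 15 (3 and 1 when adjusted over the list alone; camera adjusted p = 0.138).

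Nuclear speckle genes were measured because the series title names speckles. Of 53 genes for speckle proteins, 3 rose and 2 fell at 12 h (2 and 2 when adjusted over the list alone; camera adjusted p = 0.726, mean log2 change -0.015). SON, a core scaffold of speckles, was at 6013 ± 157 in DMSO and 5704 ± 226 at 12 h and did not pass the test (log2 fold change -0.077, limma adjusted p = 0.115). The scaffold gene SRRM2 fell by 0.20 on the log2 scale (limma adjusted p = 3.97e-06), as did the export factor THOC2 (-0.18), whereas CASC3 (0.16), SART1 (0.16) and the splicing factor SRSF5 (0.17, named after its value was seen) rose. Of the 5 speckle and paraspeckle RNAs and proteins, MALAT1, a long RNA of speckles, rose from 3428 ± 291 to 4072 ± 44.6 (log2 fold change 0.25, limma adjusted p = 0.000568), and the count was 1 also when adjusted over the list alone (camera adjusted p = 0.138, but 0.0346 after quantile normalization and 0.0262 without 12 h replicate 1, and adjusted p = 0.409 with an estimated correlation). The MALAT1 call was lost with DESeq2 (adjusted p = 0.372) and without DMSO replicate 2 (limma adjusted p = 0.153). NEAT1, the paraspeckle RNA, stood at 945.2 ± 54.3 and 965.2 ± 80.6 (limma adjusted p = 0.794).

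Of the 13 HIF pathway components, 3 fell and 1 rose at 12 h (the same numbers when adjusted over the list alone; camera adjusted p = 0.138). EPAS1, which encodes HIF-2α itself, went from 1076 ± 25.7 to 904.3 ± 5.57 (log2 fold change -0.25, limma adjusted p = 0.000321), and ELOB fell by 0.16 besides EGLN3. HIF1A, at a low level of 71.08 ± 2.70 in DMSO, was at 99.28 ± 3.11 (log2 fold change 0.48, limma adjusted p = 0.0380). That call was lost with quantile normalization (adjusted p = 0.0787), with DESeq2 (0.266) and with any 1 of the 4 libraries left out. ARNT (607.0 ± 37.6 and 603.4 ± 16.2, limma adjusted p = 0.962) and VHL (213.8 ± 21.7 and 223.4 ± 3.71, limma adjusted p = 0.740) did not pass the test. Of 20 markers of leukocytes, endothelium, fibroblasts and neurons 5 were measured, and CD68, which tumor lines also express, fell (-0.28, limma adjusted p = 0.0476; 1 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.912).

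In all, limma called 1750 of 11897 genes at 12 h, 711 higher and 1039 lower, of which 17 and 56 changed at least 2-fold. The median size of a called change was 0.25 on the log2 scale. DESeq2 on the recovered reads called 718 genes (203 higher, 515 lower), the same numbers as the authors' deposited table. Quantile normalization moved the higher share of calls from 40.6% to 50.3%, and limma called 1098, 966 and 1060 genes without DMSO replicate 1, DMSO replicate 2 and 12 h replicate 2.

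**Figure D2:**
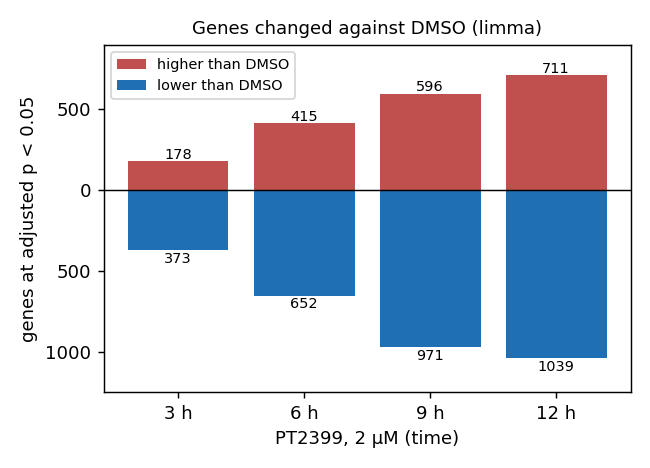
Number of genes at an adjusted p under 0.05 (vertical axis) higher (red, upward) or lower (blue, downward) than DMSO at each PT2399 time (horizontal axis), by limma over 11897 genes. Counts ran from 178 higher and 373 lower at 3 h to 711 higher and 1039 lower at 12 h.

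The early response, at 3 h, already held many of the large decreases. DDIT4 was at 375.3 ± 3.97, 5.91 times below DMSO (limma with Benjamini-Hochberg adjustment, adjusted p = 1.51e-41), F3 3.71 times, C10orf10 3.39 times, ADM 3.17 times, EGLN3 2.84 times, ERRFI1 2.82 times and VEGFA 2.12 times below it. SLC2A1 and NDRG1 were at 6966 ± 203 and 1573 ± 53.8 (log2 fold changes -0.67 and -0.58). Among genes with a mean of at least 50, the largest increase was that of SLC30A1, which reached 839.5 ± 24.9, 2.81 times above DMSO, followed by MT1X (2.42 times) and MT1F (2.09 times). Of the HIF-2 and hypoxia list 26 of 40 genes fell and 1 rose (28 and 2 when adjusted over the list alone), with a mean log2 change of -0.42 (camera adjusted p = 5.56e-47, and 0.000311 with an estimated correlation). NF-kB and cytokine genes had 8 of 19 lower and 0 higher (13 lower when adjusted over the list alone; camera adjusted p = 5.94e-12, and 0.0197 with an estimated correlation). Glycolysis had 4 of 25 lower (5 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.0936, but 0.00812 after quantile normalization, and adjusted p = 0.322 with an estimated correlation). Ribosomal protein genes had a mean of 0.056, with 1 of 47 higher (7 when adjusted over the list alone; camera adjusted p = 1.62e-08, adjusted p = 0.404 with an estimated correlation). The mitosis list (mean -0.063, camera adjusted p = 0.000137), heat shock genes (0.048, 0.0461) and matrix genes (0.051, 0.0361) passed the preset test, with an adjusted p = 0.0647, 0.455 and 0.347 in that order with an estimated correlation. The call for the last 2 lists was also lost with quantile normalization.

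Limma called 551 genes at 3 h (178 higher, 373 lower) and DESeq2 170 (43 and 127). Without DMSO replicate 1 or DMSO replicate 2, limma called 281 or 301.

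At 6 h and 9 h the largest decreases were in genes also named at 3 h and 12 h. Of the 971 genes lower at 9 h, 242 were also lower at 3 h and 500 at 6 h. Among genes with a mean of at least 50, DDIT4, F3 and C10orf10 had the largest decreases at 6 h (log2 fold changes -2.70, -1.98 and -1.79), and DDIT4, F3 and SLC2A1 at 9 h (-2.56, -2.08 and -1.87). MT1F, MT1X and SLC30A1 had the largest increases at both times, with log2 fold changes of 1.60, 1.56 and 1.18 at 6 h and 2.00, 1.78 and 1.01 at 9 h. The HIF-2 and hypoxia list had 26 of 40 genes lower and 0 higher at 6 h, also when adjusted over the list alone. At 9 h it had 27 lower and 0 higher (31 and 2 when adjusted over the list alone). Camera adjusted p-values were 1.98e-56 and 1.71e-53, and 0.000196 and 0.000225 with an estimated correlation. Cholesterol synthesis genes, which make and take up sterols, rose at these times: 7 of 24 at 6 h and 8 at 9 h, with 0 lower, also when adjusted over the list alone. Their camera adjusted p was 0.00125 at 6 h (adjusted p = 0.0877 with an estimated correlation) and 2.36e-05 at 9 h (0.0473). Glycolysis genes had 10 and 12 of 25 lower (11 and 15 when adjusted over the list alone; adjusted p = 0.00583 and 0.00384 with an estimated correlation). NF-kB genes had 13 and 14 of 19 (16 and 16 when adjusted over the list alone; adjusted p = 0.00583 and 0.00644 with an estimated correlation). Limma called 1067 genes at 6 h (415 higher, 652 lower) and 1567 at 9 h (596 higher, 971 lower), and DESeq2 410 and 663. Counts at 6 h were 572, 597, 607 and 556 without DMSO replicate 1, DMSO replicate 2, 6 h replicate 1 and 6 h replicate 2. At 9 h they were 917, 897, 841 and 915 without DMSO replicate 1, DMSO replicate 2, 9 h replicate 1 and 9 h replicate 2. Quantile normalization moved the higher share at 9 h from 38.0% to 48.4%, with 631 genes lower.

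**Figure D3:**
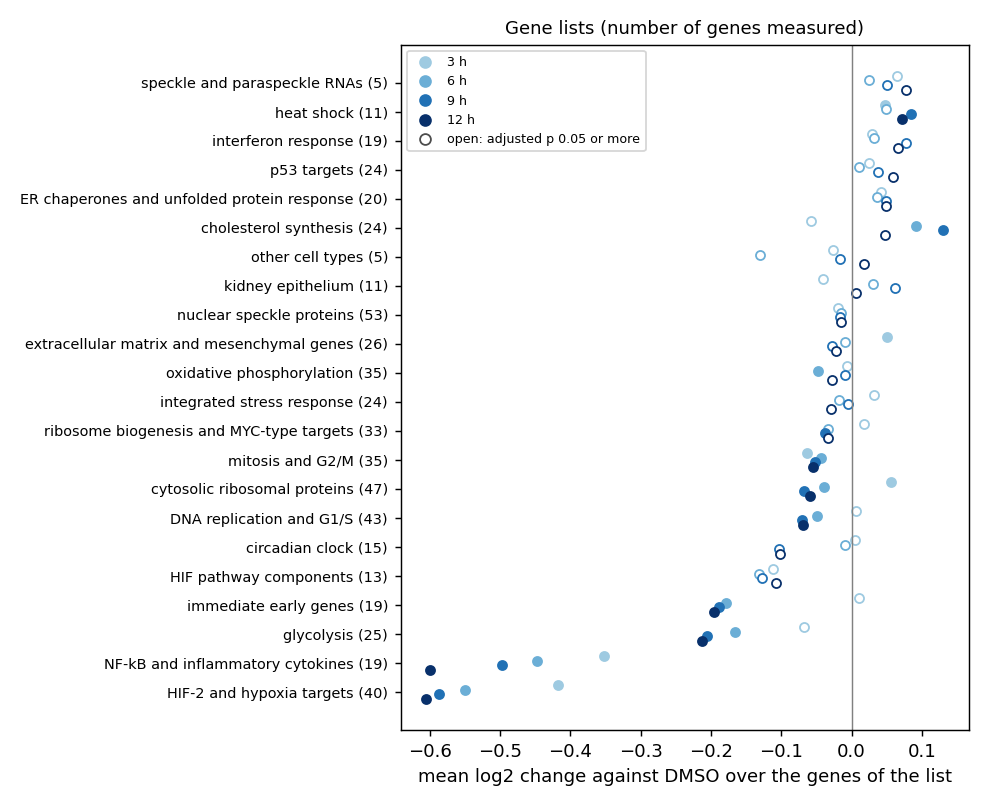
Mean log2 change against DMSO (horizontal axis) of the 22 tested gene lists at 3, 6, 9 and 12 h, with the number of measured genes in brackets; filled points had a camera adjusted p under 0.05 at the preset correlation, open points did not. HIF-2 and hypoxia targets (-0.42 at 3 h, -0.60 at 12 h) and NF-kB genes (-0.35 and -0.60) lay farthest from 0.

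The direct comparison of 12 h with 3 h, in which the DMSO libraries cancel out, asks which genes kept moving. DMSO was collected at 12 h only. This comparison, like the others between PT2399 times, therefore also holds any change of untreated cells over these hours. NDRG1 fell further by 1.32 on the log2 scale (limma with Benjamini-Hochberg adjustment, adjusted p = 8.77e-31), RASA3, a GTPase-activating protein for Ras, by 1.28 (1.81e-17) and SLC2A1 by 1.21 (3.88e-40). FGFR2 rose by 1.11 (7.04e-18), MT1F by 1.08 (4.71e-09) and the zinc finger gene ZSCAN31 by 0.96 (4.36e-05). RASA3 and FGFR2 crossed the DMSO level: RASA3 was at 266.0 ± 4.36 in DMSO, 399.9 ± 23.2 at 3 h and 164.6 ± 18.7 at 12 h, and FGFR2 at 294.9 ± 20.1, 235.1 ± 11.8 and 510.2 ± 28.2. The FGFR2 decrease at 3 h (limma adjusted p = 0.00642) was lost with DESeq2 (0.310), without DMSO replicate 1 (0.203) and without 3 h replicate 1 (0.106). DDIT4, EGLN3 and ERRFI1 did not pass the test of this difference (limma adjusted p = 0.290, 0.179 and 0.486); of their 12 h log2 change, 95.6%, 90.8% and 96.5% was present at 3 h. The share was 75.7% for VEGFA, 50.3% for CCND1, 35.6% for SLC2A1 and 30.6% for NDRG1.

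Glycolysis genes fell between 3 h and 12 h, with 13 of 25 lower and 1 higher at 12 h than at 3 h (14 and 2 when adjusted over the list alone; camera adjusted p = 4.52e-13, and 0.00481 with an estimated correlation). The HIF-2 and hypoxia list had 15 of 40 lower and 4 higher (19 and 6 when adjusted over the list alone; 7.64e-15, and 0.00481 with an estimated correlation), and NF-kB genes 9 of 19 lower (10 when adjusted over the list alone; 6.10e-07, and 0.0495 with an estimated correlation). Ribosomal protein genes had 31 of 47 lower and 0 higher (42 and 0 when adjusted over the list alone), with a mean of -0.11, or -0.059 after quantile normalization (camera adjusted p = 4.01e-21, adjusted p = 0.125 with an estimated correlation). Limma called 1339 genes in this contrast (610 higher, 729 lower) and DESeq2 463 (148 and 315). After quantile normalization the majority turned, with 572 higher and 541 lower, and with 699 rising and 653 falling in the linear trend over the PT2399 times. Limma called 857 without 3 h replicate 1 and 857 without 12 h replicate 2. With a linear trend per hour over the 4 PT2399 times, 1628 genes passed (762 rising, 866 falling), 586 with DESeq2, and 1067 or 1051 by limma without 3 h replicate 1 or 12 h replicate 2. SLC2A1 had a slope of -0.13 per h on the log2 scale (limma adjusted p = 2.88e-41) and NDRG1 of -0.15 (2.05e-33). Successive times were compared after the data were seen. Limma called 312 genes between 3 h and 6 h (118 higher, 194 lower), 95 between 6 h and 9 h (29 and 66) and 5 between 9 h and 12 h, where 609 had an unadjusted p under 0.05. DESeq2 called 66, 34 and 0 and limma after quantile normalization 186, 58 and 3. Between 3 h and 6 h limma called 132, 123 and 131 without 3 h replicate 1, 6 h replicate 1 and 6 h replicate 2. Between 6 h and 9 h it called 18, 32, 27 and 22 without 6 h replicate 1, 6 h replicate 2, 9 h replicate 1 and 9 h replicate 2. Between 9 h and 12 h it called 0 without either 9 h library, 9 without 12 h replicate 1 and 3 without 12 h replicate 2. Among the 5 called between 9 h and 12 h, and named after their values were seen, were INSIG1 (-0.26), which holds back sterol synthesis, TGM2 (-0.16), the Notch ligand JAG1 (0.23) and AHNAK (0.12).

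**Figure D4:**
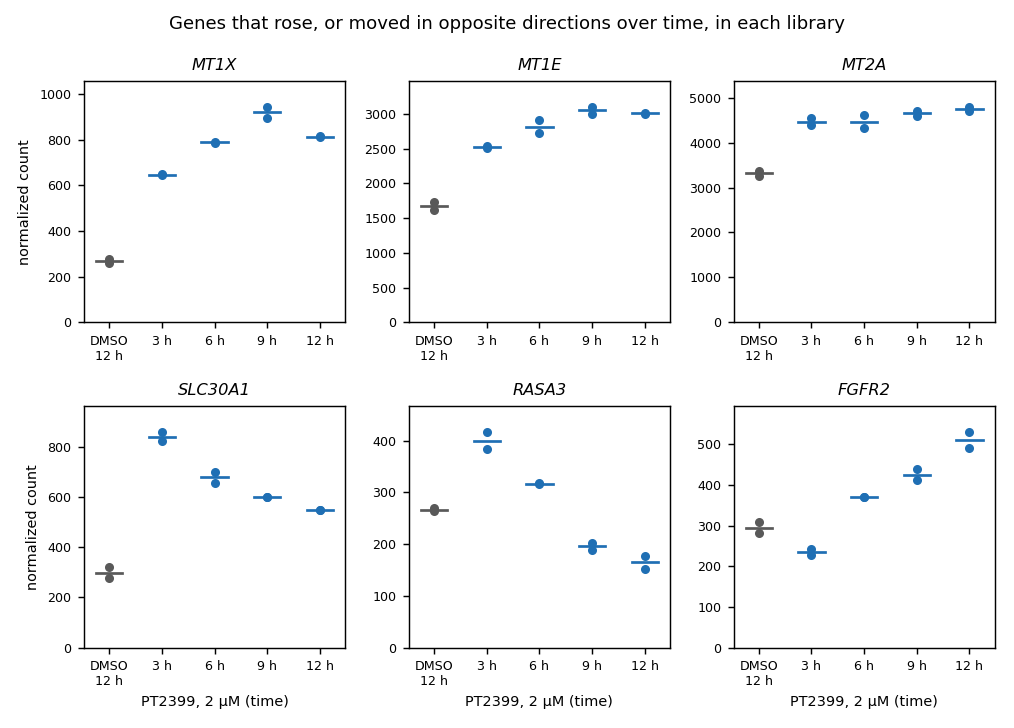
Normalized count (vertical axis, from 0) of 6 genes in DMSO at 12 h (grey) and after 3, 6, 9 and 12 h of 2 µM PT2399 (blue); points are libraries and bars are means of 2. MT1X, MT1E and MT2A (chosen after its values were seen) lay above DMSO at all 4 times, SLC30A1 went from 839.5 at 3 h to 547.9 at 12 h, and RASA3 and FGFR2 crossed the DMSO level in opposite directions.

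Calls overlapped between times. Of the 373 genes lower at 3 h, 228 were also lower at 12 h, and of the 178 higher, 76 were also higher, against 32.6 and 10.6 for independent lists of these sizes. Of the 971 lower at 9 h 726 were lower at 12 h, and of the 596 higher 391, against 84.8 and 35.6. Simulated groups without an effect shared 0 calls on average, but the contrasts share the DMSO libraries, and part of the excess may come from the shared controls. Across genes, which are not independent replicates, log2 fold changes at 3 h and 12 h had Pearson's r of 0.569 and Spearman's rho of 0.457, and those at 9 h and 12 h 0.811 and 0.759. Simulated groups without an effect gave an r of up to 0.501 from the shared controls alone, and the covariance lay above the simulated one by 0.0176 and 0.0359. In all, 200 genes were lower at all 4 times and 55 higher at all 4, and 24 were called higher at one time and lower at another, among 2573 called at any time.

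The authors' deposited tables, from DESeq2, called 170 genes at 3 h (43 higher with PT2399, 127 lower), 410 at 6 h (94 and 316), 666 at 9 h (152 and 514) and 718 at 12 h (203 and 515). At 9 h the table also called the entry for reads outside genes, 1 of the 2 entries that name no gene, which is not counted here. Each of these genes was also called by limma in the same direction. Limma called another 381, 657, 901 and 1032 genes in time order. Log2 fold changes of the authors' deposited tables and of limma correlated across genes with r between 0.994 and 0.997.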

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

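Chosen only after the result was seen were both metallothionein tests, the tests of the added metallothionein list, and the counts of genes that moved back with DESeq2 or with 1 library left out.

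Metallothionein genes rose with PT2399, and the increase grew between 3 h and 12 h for MT1F (1.08 on the log2 scale), MT1X (0.33), MT1E (0.25) and MT1G (1.36, named after its values were seen, from 1 read in the 2 DMSO libraries), whereas SLC30A1 moved back (-0.61). With SLC30A1, 6 of 7 genes were higher and 0 lower at 3 h and at 12 h, also when adjusted over the list alone, with a mean of 1.24 and 1.58 (adjusted p = 0.000116 and 0.000267 with an estimated correlation). Reads moving between paralogs would leave the sum of the family in place. The sum rose from 5372 ± 150 in DMSO to 7831 ± 112 at 3 h and 8899 ± 64.1 at 12 h (SD, n = 2). Its log2 change was 0.54 at 3 h and 0.73 at 12 h. Since DMSO was matched in time at 12 h, time since handling of the cultures would not give a change there. The mean of the 6 metallothionein genes was 1.20 at 3 h and 1.69 at 12 h. The difference of 0.49 had an SE of 0.242 over the 6 genes, which are not independent replicates. A part of the 3 h change from handling was not tested. The genes were picked after their increases were seen, so the results of both tests were largely known beforehand. A release or uptake of zinc after HIF-2 inhibition remains a hypothesis without a test, as does an effect of the compound apart from HIF-2.

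Of the genes called at 3 h, 142 (57 higher, 85 lower) moved back by 12 h in the direct comparison of the 2 times, 113 of them without a call at 12 h. The other 29 were called at 12 h, 15 of them in the direction opposite to that at 3 h. Examples, named after their values were seen, were TSC22D3 (-0.45 from 3 h to 12 h), RGS2 (-0.75), ELF3 (0.55), SOX9 (0.53), PNRC1 (0.67) and THRB (0.79). Of these, RGS2 and PNRC1 were without a call at 12 h. TSC22D3 (0.38 against DMSO at 12 h), ELF3 (-0.56) and SOX9 (-0.57) were still called in their 3 h direction. THRB crossed the DMSO level, from -0.40 at 3 h to 0.39 at 12 h. Noise in the 3 h libraries, which both contrasts share, was simulated as independent between genes, with the variances that limma estimated. A deviation shared across genes, or a larger spread, therefore stays open. Independent noise of that size is argued against, since 100 simulations without a transient gave at most 11 such genes. The number was 29 with DESeq2, 76 without DMSO replicate 1, 86 without DMSO replicate 2 and between 97 and 145 without any other 1 of the libraries used. A short response to the drug and one to the handling of the cultures cannot be told apart, since no DMSO library was collected at 3 h and 79.6% of these genes were without a call at 12 h, where DMSO was matched in time.

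Genes of cytosolic ribosomal proteins were lower at 12 h than at 3 h, with a mean of -0.11, or -0.059 after quantile normalization, and an adjusted p = 0.125 with an estimated correlation, at which the list was no longer called. Genes among them were RPS24 (-0.18), RPLP0 (-0.16) and RPL3 (-0.16). A single library as the cause is argued against, since the median of -0.11 was -0.094 without 12 h replicate 1, the smallest decrease with any 1 of the 4 libraries left out. Genes matched on transcript length and abundance also fell (median -0.047, interval -0.071 to -0.020), by less than the ribosomal genes. The match was on both, so an effect of short transcripts cannot be separated from one of abundance. Either stays open for part of the decrease. Across 11107 genes, transcript length and the change from 3 h to 12 h had a Spearman's rho of 0.038. An effect of HIF-2 loss on ribosomal genes was not tested, nor was one of time in culture.

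In all, values after 12 h of PT2399 differed from those after 3 h for 1339 genes by limma. With no DMSO library at 3 h, a change in the drug's effect and one with time in culture cannot be told apart. This holds for these genes and for the lists and genes that follow. Other lists whose mean differed between the 2 times, 12 h minus 3 h, were HIF-2 and hypoxia targets (-0.19), glycolysis (-0.14), NF-kB and cytokines (-0.25), immediate early genes (-0.20), DNA replication (-0.075), matrix genes (-0.073), ribosome biogenesis (-0.051) and cholesterol synthesis (0.10). With an estimated correlation the last 5 were no longer called (adjusted p = 0.147, 0.1002, 0.109, 0.0887 and 0.0887), and after quantile normalization neither were matrix genes (0.643) and ribosome biogenesis (0.0733). Other named genes whose change differed were lower at 12 h than at 3 h (NDRG1 -1.32, RASA3 -1.28, SLC2A1 -1.21, MYEOV -0.93, CCND1 -0.73, SEMA4B -0.71, TGM2 -0.67, CXCL8 -0.54, SLC7A5 -0.51, TGFA -0.48, ICAM1 -0.45, TEF -0.43, FOSL1 -0.41, TNFRSF10B -0.41, SLC3A2 -0.40, TRIB3 -0.37, ADM -0.37, VEGFA -0.35, MMP2 -0.33, HK2 -0.32, ENO2 -0.27, HERPUD1 -0.27, F3 -0.26, ALDOA -0.26, TGFB1 -0.25, LDHA -0.22, INSIG1 -0.22, KRT18 -0.21, IGFBP3 -0.19, RRM2 -0.16, MCM7 -0.16, POLE -0.16, UBE2C -0.15, SRRM2 -0.14, MCM4 -0.13 and CDC20 -0.11). Higher were FGFR2 1.11, ZSCAN31 0.96, TP53I3 0.65, KCNJ16 0.65, PCLO 0.64, SLC25A20 0.46, CDH6 0.42, FBN1 0.41, JAG1 0.40, SLC7A11 0.37, FDFT1 0.33, VLDLR 0.32, RRM2B 0.26, THBS1 0.25, NFIL3 0.24, GCLM 0.23, TXNRD1 0.23, NQO1 0.23, IDI1 0.18, HMGCS1 0.18, HSPH1 0.15, DNAJA1 0.12, HSP90AA1 0.098 and AHNAK 0.088. Reads ambiguous between genes, which no test used, made up 2.907%, 2.914% and 2.906% of the libraries at 3, 6 and 9 h on average, above the 2.890% to 2.892% of the DMSO libraries. At 12 h the 2 libraries had 2.874% and 2.918%.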

How the results depend on the processing

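Chosen only after the result was seen were the tests of successive PT2399 times, and those that count the genes that moved back by 12 h (142 by limma) with DESeq2 (29) or without 1 library (76 to 145, with 76 and 86 without DMSO replicate 1 and DMSO replicate 2). DESeq2 on recovered reads called fewer genes: 170 at 3 h (43 higher, 127 lower), 410 at 6 h (94, 316), 663 at 9 h (152, 511), 718 at 12 h (203, 515), 463 for 12 h against 3 h (148, 315) and 586 with a trend (201, 385), all also called by limma. In simulation DESeq2 missed more changed genes than limma and made fewer false calls. That simulation held no larger spread at 12 h, so it cannot decide which count is nearer the truth there. Against 551, 1067, 1567, 1750, 1339 and 1628 by limma, edgeR called 499, 1125, 1709, 1809, 1228 and 1498, and TMM scaling 550, 1061, 1560, 1736, 1332 and 1611. Limma on the libraries of each contrast only called 615, 1395, 1951, 1623, 978 and 1543. The higher share of calls with DESeq2 was 25.3%, 22.9%, 22.9%, 28.3%, 32.0% and 34.3%, against 32.3%, 38.9%, 38.0%, 40.6%, 45.6% and 46.8%; the share with quantile normalization was 48.4% at 9 h, with 631 lower, and 50.3% at 12 h. Quantile normalization also turned the majority for 12 h against 3 h (572 higher, 541 lower) and for the trend (699, 653).

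Quantile normalization turned the sign of the ribosomal protein list at 6 h (0.013) and 9 h (0.0041), of the ribosome biogenesis list at 9 h (0.0059, from -0.038, its call lost with adjusted p = 0.875) and of RPL3 at 9 h (0.037) and 12 h (0.014). With a minimum mean of 50 the immediate early genes at 3 h went from 0.010 to -0.060 and gained a call. That minimum leaves the log2 changes of the kept genes as they were, so this mean turned because low genes left the list. The cause of the turns with quantile normalization was not tested. Correlations of fold changes moved with a pseudocount of 5 (3 and 6 h 0.670, 6 and 9 h 0.786, 6 and 12 h 0.745, 9 and 12 h 0.825) and with a minimum mean of 50 (3 and 6 h 0.727, 3 and 9 h 0.626, 3 and 12 h 0.595, 6 and 9 h 0.834, 6 and 12 h 0.794, 9 and 12 h 0.880). They moved also with quantile normalization (6 and 9 h 0.759, 6 and 12 h 0.714, 9 and 12 h 0.797). The reported ones were 0.659 (3 and 6 h), 0.602 (3 and 9 h), 0.569 (3 and 12 h), 0.777 (6 and 9 h), 0.734 (6 and 12 h) and 0.811 (9 and 12 h). The cause of these moves was not tested. Without 1 DMSO library they were 0.716 to 0.731, 0.664 to 0.683, 0.635 to 0.655, 0.811 to 0.818, 0.774 to 0.783 and 0.838 to 0.845 for 3 and 6 h, 3 and 9 h, 3 and 12 h, 6 and 9 h, 6 and 12 h, and 9 and 12 h. A single control raises them by construction: simulated groups without an effect gave up to 0.667, which the values for 3 and 12 h, and that for 3 and 9 h without DMSO replicate 1 (0.664), did not exceed. The covariance for 3 and 12 h lay above the simulated one by 0.0160 and 0.0197 without DMSO replicate 1 and DMSO replicate 2, against 0.0176.

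Leaving out 1 library, whose partner is then assumed to vary like the other groups, gave 281 to 400 genes at 3 h (higher 94 to 145, lower 187 to 292), 556 to 607 at 6 h (181 to 219, 363 to 426), 841 to 917 at 9 h (254 to 324, 578 to 640), 966 to 1605 at 12 h (387 to 607, 579 to 998). It gave 857 to 1253 for 12 h against 3 h (366 to 526, 446 to 727) and 1051 to 1512 for the trend (457 to 698, 567 to 851). Counts fell by over 1.5 times without DMSO replicate 1 (281, 572, 917 and 1098 in time order), DMSO replicate 2 (301, 597, 897, 966) and 3 h replicate 1 (857 against 3 h, trend 1067). They fell likewise without 6 h replicate 1 (607), 6 h replicate 2 (556), 9 h replicate 1 (841), 9 h replicate 2 (915) and 12 h replicate 2 (1060 against DMSO, 857 against 3 h, trend 1051). Without 12 h replicate 1 they were 1605, 1253 and 1512, so the number of libraries alone does not account for the fall without 12 h replicate 2; its cause was not tested.

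With the replicate number as a block, limma called 577, 1112, 1617, 1823, 1404 and 1693 genes. Libraries of one number showed no strong common deviation (correlations of -0.039 to 0.066 over 10 pairs of groups). Counting noise could hide a weaker one, so these values cannot decide whether the numbers pair the libraries. The HIF-2 list kept its direction and its call in all alternatives run, with a mean of -0.58 to -0.64 at 12 h. For the named genes, many picked for large changes, 8605 of 9119 values under an alternative kept direction and call. Another 444 lost the call, 68 gained one and 2 changed sign. Of 2494 values of lists these numbers were 2358, 70, 62 and 4. Genes and lists that stayed without a call count as kept. Of all genes that limma called in a contrast, 66.8% to 76.8% were also called after quantile normalization. The share was 30.9% to 42.3% with DESeq2 and 89.3% to 99.9% with edgeR. Counting noise limits low genes: with 2 libraries a group, genes under a mean of 10 were not tested, and 80.8% of simulated changes of 0.5 at 12 h were recovered.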

Other observations

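All tests in this part apart from that on AU-rich elements were chosen after results had been seen, and so were the genes named here apart from SLC7A11.

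Part of the NRF2 targets, genes of the response to oxidative stress, were higher with PT2399. In a list of NRF2 targets written after the data were seen, 10 of 18 measured genes were higher at 12 h and 0 lower (12 and 0 when adjusted over the list alone), with a mean log2 change of 0.30 (camera adjusted p = 7.12e-11, and 0.00221 with an estimated correlation). They included the glutathione synthesis gene GCLM (1641 ± 27.9 to 2138 ± 12.7, SD, n = 2), the quinone reductase NQO1 (1982 ± 0.843 to 2385 ± 83.7), TXNRD1 (0.28), OSGIN1 (0.70) and SLC7A11 (0.44). The heme oxygenase gene HMOX1 was higher by 0.45 at 3 h and 0.41 at 12 h. At 3 h 3 of the 18 were higher (4 when adjusted over the list alone; adjusted p = 0.0224 with an estimated correlation), and the list rose further between 3 h and 12 h (mean 0.19, adjusted p = 0.0224 with an estimated correlation).

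Genes of fatty acid oxidation, also listed after the data were seen, had 4 of 19 higher and 0 lower at 12 h (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0186, adjusted p = 0.0980 with an estimated correlation). The carnitine carrier SLC25A20 went from 96.86 ± 8.59 to 160.0 ± 8.20 (SD, n = 2). From 3 h to 12 h 6 of the 19 were higher and 0 lower (8 and 0 when adjusted over the list alone; adjusted p = 0.0363 with an estimated correlation). The 24 genes called higher at one time and lower at another included THRB, a thyroid hormone receptor, at 195.8 ± 13.5 in DMSO, 147.6 ± 0.729 at 3 h and 256.7 ± 6.37 at 12 h (SD, n = 2).

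Genes that fell reached their 12 h level at different speeds, and one hypothesis is that AU-rich elements, which shorten the life of messenger RNA, could set this speed. Among 131 genes lower by at least 0.5 on the log2 scale at 12 h, the median share of the decrease present at 3 h was 55.3% (quartiles 30.7% and 80.9%). For 122 of them with an annotated 3' untranslated region, the density of ATTTA pentamers and this share had a Spearman's rho of 0.0894 (bootstrap interval -0.087 to 0.27, permutation p = 0.328; Pearson's r 0.053) across genes, which are not independent replicates. The interval holds both 0 and values above 0.1, so the test leaves the hypothesis open.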
